A study of Mus musculus with 2 samples.

How the data were processed

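Immune cells from mouse tumours were profiled by droplet single-cell RNA sequencing in 2 libraries, named Arg and Control. Per the series' design text, BALB/c mice aged 5 weeks received either a normal diet or an isocaloric diet without arginine, starting 1 week before CT26 cells, a mouse colorectal carcinoma line, were injected under the skin, and tumours were taken on day 20. The library named Arg was read as the arginine-deficient arm from that text, because its own label gives no diet. How many mice entered each library is not given in the sources used here. Per the labels' protocols, tumours were dissociated with DNase I, collagenase IV and a neutral protease, strained, freed of red cells and enriched for CD45-positive cells with magnetic beads. Cells were then loaded on the 10x Chromium 3′ v3 system and sequenced on a NovaSeq 6000.

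The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization, for 32285 genes. Per the file headers they were written by Cell Ranger 7.0.1, whereas the submitters' processing notes name Cell Ranger 2.2.2 and the genome build GRCm38, and the difference was not resolved. Whether intronic reads were counted is not given in the sources used here, so levels of genes with long introns or with overlapping neighbours depend on a setting that is not known. The deposited matrices held 14540 barcodes in the Arg library and 14343 in the Control library, each with at least 500 UMIs. Total counts were 155927693 and 191505551 UMIs. Gene positions came from GENCODE M21 on GRCm38, in which 32158 of the 32285 gene identifiers were found (99.6%).

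Barcodes with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept, which left 13875 and 13487. All 665 and 856 barcodes left out exceeded the mitochondrial limit. Scrublet, run per library with an expected doublet share of 8%, called 884 (6.37%) and 687 (5.09%) doublets, which were removed. This left 12991 Arg and 12800 Control cells, with medians of 8294 and 10021 UMIs.

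Counts were scaled to 10000 UMIs per cell and log-transformed. Clusters were made from 2000 variable genes, 30 principal components, 20 nearest neighbours and the Leiden method at resolution 1, on both libraries together and without batch correction, and T and NK clusters were clustered again by themselves. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM scaling factors. The random seed was 1.

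Clusters were named from 22 sets of marker genes. A cluster took the name of the set with the highest mean log2 fold over the other clusters, provided that this mean was at least 0.5, that 3 or more markers were each found in at least 20% of its cells, and that it held at least 20 cells. It stayed unnamed where another lineage had more detected markers, where its cells were shallow and no own marker led it, or where its 10 leading genes held more markers of another class than of its own. The names mean "like" (CD8 T-like, macrophage-like) and are written without that suffix. B and plasma clusters were pooled as B lineage. The marker sets were fixed in advance, but these thresholds were set after the clusters had been seen. Judging T and NK clusters by their 10 leading genes against all other clusters, which keeps cluster L9 in the CD8 T class, was also decided after its effect was seen. So was counting the markers of other T cell classes, which keeps cluster L5 out of it. Cluster L5 had Cd8a in 96.2% and Trdc in 1.33% of its cells. It had the gamma-delta T marker Tcrg-C2 among its leading genes, found in 39.8% of its cells, in 33.3% of those of the CD8 T cluster L1 and in 21.9% of those of the gamma-delta T cluster. Values with cluster L5 are therefore given beside the share of CD8 T cells and their Cd200 level.

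With 1 library per diet, cells are not replicates. No test was run, and no p-value, standard error or count of changed genes was made. Shares of cells have exact Clopper-Pearson 95% intervals, and summed counts have exact Poisson 95% intervals. All intervals cover counting error only and not the variation between mice, tumours or preparations. Those of summed counts treat every UMI as independent, so they also leave out variation between cells and are too narrow where few cells hold many UMIs. In CD4 T cells of the Arg library, for example, 163 Cd200 UMIs came from 34 of 232 cells. Per class and library, counts were summed and divided by the class total to give CPM, and the log2 ratio of Arg over Control was taken after adding 5 CPM to each. Folds in brackets are ratios of the CPM themselves. Classes with at least 100 cells in both libraries were compared. Shares of cells with a Cd200 UMI were taken after thinning each cell at random to 2000 UMIs and leaving out shallower cells. Cells with and without a Cd200 UMI were compared in a separate draw of the same depth, with 50 CPM added and a minimum of 50 CPM, which were set after the data had been seen.

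The classes, lists, markers, thresholds for genes and main settings were otherwise chosen before the data were examined. For CD8 T cells and macrophages, the classes the study's title names, the text names the 10 genes with the highest and the 10 with the lowest log2 ratio, and for every other class 3 of each. Such genes needed at least 50 CPM in the library where they were higher and 30 UMIs in total. They also needed a level of at least 1 part in 5 of their highest in any other named class of that library, as a guard against free RNA. Mitochondrial, ribosomal protein, haemoglobin, T cell receptor and immunoglobulin genes and numbered gene models were left out. Cd200, Cd200r1, Arg1, Nos2 and Slc7a1 were named in any case. Some genes that these rules pick are not reported here.

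There were 25 gene lists: CD200 and its receptors, arginine transport and metabolism, amino acid starvation response, T cell cytotoxicity and effector cytokines, T cell exhaustion, naive, stem-like and memory T cells, T cell activation and costimulation, regulatory T cell effector genes, MHC class I antigen processing, cross-presentation, MHC class II antigen presentation, costimulation and T cell attracting chemokines, interferon gamma response, type I interferon response, inflammatory macrophage, alternatively activated macrophage, lipid-associated macrophage and lysosome, hypoxia and glycolysis, nuclear-encoded oxidative phosphorylation, cholesterol synthesis, cell cycle, neutrophil maturation and granules, suppressive neutrophil, dissociation stress, and complement. A member counted as measured at 10 CPM or more in either library, and the guard against free RNA was not applied to members. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is not a p-value. From each list the text names the 2 measured members furthest above and the 2 furthest below 0.

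The steps were tested on simulated class sums with 200 genes changed by known folds. The sums were Poisson draws, the model that the intervals assume, so the shares below check the calculation only. They do not show that the intervals hold for these cells, because no cells, clusters or free RNA were simulated. In CD8 T cells, over 7960 genes, the intervals held the true fold for 96% of genes changed 2-fold, 96% of genes changed 4-fold and 95.3% of unchanged genes. In macrophages, over 7735 genes, these shares were 95%, 93% and 95.5%. A list of 20 genes raised 2-fold had a median log2 ratio of 0.88 in CD8 T cells, where the true value was 0.88, and 0.84 in macrophages, where it was 0.83.

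The alternatives were a stricter cell filter (at least 500 genes, at most 5% mitochondrial UMIs), no filter beyond 100 genes, doublets kept, resolutions 0.5 and 2, and genes centred within libraries before clustering. Others were thinning to 1000 UMIs or none, TMM or median-of-ratios scaling, equal weight per cell, 1 CPM added, and a list minimum of 50 CPM or none. Alternatives added after seeing the data were no minimum score for names, the share among immune cells, pooling of monocytes and macrophages, CD8 T cells without cluster L9, 1 common mix of a class's clusters in both libraries, and not counting markers of the same lineage when leading genes are checked, alone, with doublets kept or at resolution 0.5. Clusters that took no name entered no comparison of genes, with these exceptions. Cluster 2, which lay between monocytes and macrophages, was part of their pool, so every value given with monocytes pooled includes it. Cluster L5 was used for Cd200, and unnamed T and NK clusters entered the sum of Ifng UMIs.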

Results

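Single-cell transcriptomes were collected from the CD45-positive fraction of subcutaneous CT26 tumours in BALB/c mice. The mice received a normal diet (the control library) or an isocaloric diet lacking arginine (the library labelled Arg, called arginine-deficient here on the series' design text), with 1 library per diet. The arginine-deficient library held 155927693 UMIs in 14540 barcodes and the control library 191505551 in 14343. After filtering and doublet removal, 12991 and 12800 cells remained, with medians of 8294 and 10021 UMIs. Because each diet had 1 library, no difference has a replicate check. Every comparison is between these libraries and not between the diets, and the intervals cover counting error only.

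The makeup of the sorted cells was compared first, to ask which immune cells differed in abundance between the diets. NK cells, CD4 T cells, regulatory T cells, monocytes, conventional type 2 dendritic cells (cDC2) and mast cells took larger shares of the arginine-deficient library. CD8 T cells, macrophages and neutrophils took smaller ones. NK cells were 8.78% (8.30–9.28; 1141 cells) of the arginine-deficient library and 4.91% (628 cells) of the control library, a ratio of 1.79. CD4 T cells were 1.79% and 0.891%, and regulatory T cells, which restrain other T cells, were 2.17% and 1.27%. The cDC2 class, which presents antigen mainly to CD4 T cells, was 4.40% (571 cells) against 1.38% (176 cells), a log2 ratio of 1.68 that was 1.01 under the stricter cell filter and 0.9958 without one. Mast cells were 1.35% against 0.438% and neutrophils 1.77% against 3.45%. The cDC1 class, specialised in cross-presentation, differed little (1.24% and 1.34%), as did plasmacytoid dendritic cells (1.45% and 1.27%) and mature dendritic cells (0.770% and 0.648%). B lineage cells were 0.477% and 0.289%, and gamma-delta T cells 0.169% and 0.0781%.

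CD8 T cells made up 7.81% (7.35–8.28; 1014 cells) of the arginine-deficient library and 10.4% (9.83–10.9; 1325 cells) of the control library, a ratio of 0.754 (0.697–0.815). With cluster L5, a CD8-positive cluster left unnamed, the shares were 8.65% and 13.0%. The direction of this share turned when doublets were kept (log2 ratio 1.004) and at resolution 0.5 (1.10), where CD8-positive clusters led by a gamma-delta T marker lost their name by construction. It also turned at resolution 2 (0.05), where the cause was not tested. Macrophages were 27.1% (3518 cells) against 36.9% (4720 cells) and monocytes, their blood-borne precursors, 16.8% against 10.4%. Pooled with cluster 2, which lay between them and took no name (11.5% and 4.21%), monocytes and macrophages made up 55.4% and 51.5% of kept cells and 57.6% and 58.3% of immune cells. Without that line the direction thus turned among all kept cells and not among immune cells. The log2 ratio of the macrophage share, −0.45, was −1.24 at resolution 0.5 and −0.66 under the stricter cell filter. It was −0.31 with doublets kept, −0.28 without a cell filter and only −0.03 with genes centred within libraries. Cluster 12, also unnamed and with a median of 790.0 UMIs, held 2.32% and 3.59% of cells. Classes that should lack CD45, left after the bead sort that acts on every share, were tumour epithelial cells (3.22% against 9.49%) and fibroblasts (0.554% against 2.26%; log2 ratio −2.03, or −1.37 at resolution 0.5).

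**Figure D1:**
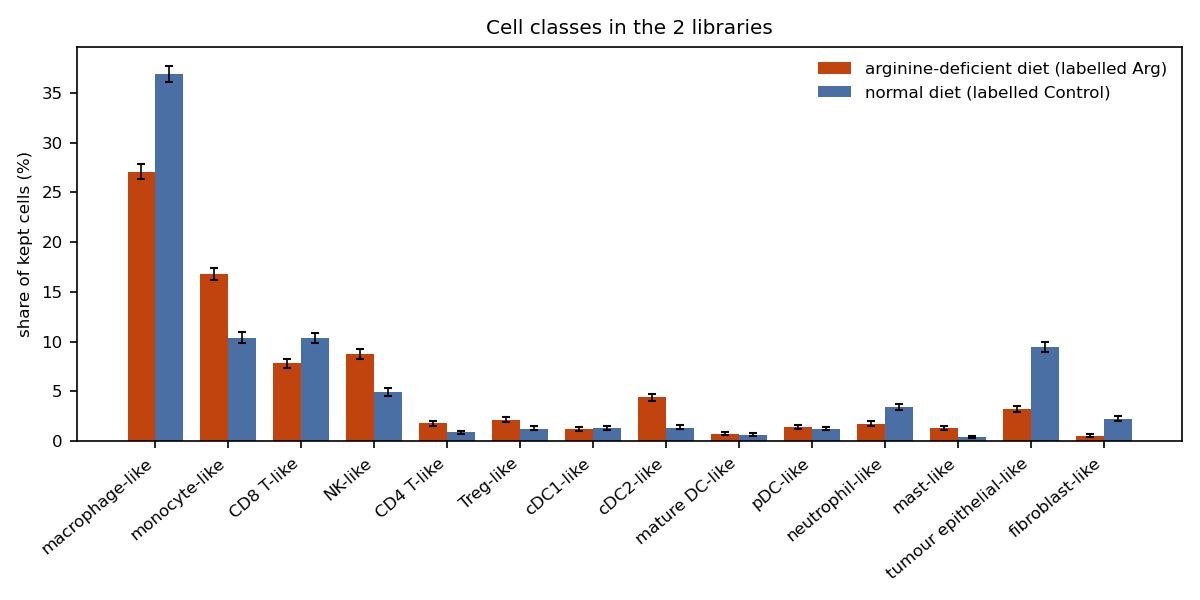
Share of kept cells per named class (percent) in the arginine-deficient and control libraries, with exact Clopper-Pearson 95% intervals. NK cells stood at 8.78% against 4.91% and macrophages at 27.1% against 36.9%.

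Cd200, which the study's title places on the CD8 T cells of interest, encodes a membrane glycoprotein that engages an inhibitory receptor on myeloid cells. Cd200 (ENSMUSG00000022661) lies on chromosome 16, 45382135–45409053, minus strand, in GRCm38. CD8 T cells of the arginine-deficient library carried 163 CPM of Cd200 (155–172; 1343 UMIs) against 92.2 CPM (86.6–98.2; 984 UMIs) in the control library, 1.77-fold more (1.63–1.93). After thinning to 2000 UMIs per cell, 18.7% of CD8 T cells (16.3–21.3; 182 of 974) had a Cd200 UMI in the arginine-deficient library and 13.1% (11.3–15.1; 170 of 1297) in the control library, with 40 and 28 shallower cells left out. Without thinning the shares were 41.7% and 33.4%, at medians of 7188 and 7373 UMIs. With cluster L5 the levels were 160.4 and 84.9 CPM and the thinned shares 20.1% and 13.2%.

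Background was read in cells that should lack Cd200. NK cells, with median depths of 5634 and 7082 UMIs, had a thinned share of 0.548% (6 of 1095) and 0.331% (2 of 605). Neutrophils (medians 2202 and 2176 UMIs) had 2.17% (3 of 138) and 1.52% (4 of 263), and macrophages (medians near 10030 and 12824 UMIs) 1.54% and 0.416%. Mature dendritic cells carried the most Cd200, at 316 and 310.3 CPM. Plasmacytoid dendritic cells had 209 and 122 CPM, regulatory T cells 126 and 101 CPM, and CD4 T cells 115 and 69.8 CPM.

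The CD8 T class was made of different clusters in the libraries. Cluster L1 held 65.9% of it in the control library and 6.41% in the arginine-deficient library, where clusters L4 (38.7%) and L3 (34.6%) held most. Cd200 was dense in clusters L4 (197 and 217 CPM) and L9 (309.9 and 260 CPM), lower in L1 (85.6 and 61.6 CPM) and sparse in L3 (3.75 and 4.96 CPM). Within a cluster the fold was 1.39 (1.01–1.88) in L1, 0.907 (0.774–1.07) in L4 and 1.19 (1.04–1.37) in L9, and 2.11 (1.81–2.46) in the unnamed L5. At 1 common mix of the clusters Cd200 stood at 122 CPM against 109.7 CPM, 1.11-fold (0.988–1.25), or 1.22-fold (1.11–1.35) with L5. The log2 ratio of 0.79 was 0.14 with doublets kept and 0.12 at resolution 0.5, where the ratio of thinned shares, 1.43 in the class as named, was 1.08 and 0.95.

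**Figure D2:**
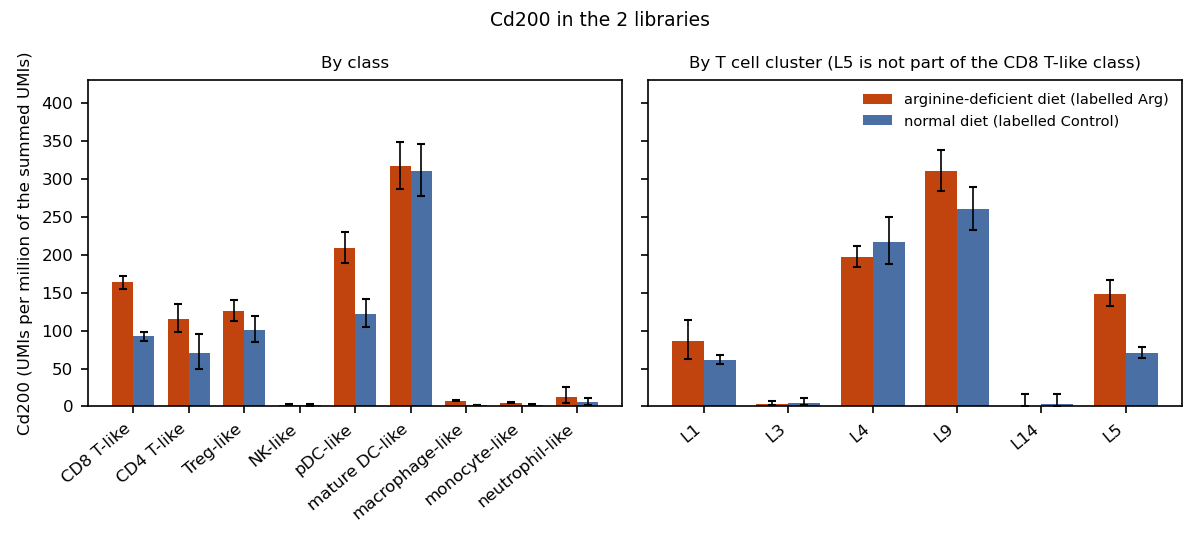
Bars give the Cd200 level (CPM, with exact Poisson 95% intervals) in the arginine-deficient and control libraries, by class on the left and by T cell cluster on the right. CD8 T cells stood at 163 against 92.2 CPM, and inside cluster L4 the order was the other way, at 197 against 217 CPM.

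Gene groups in CD8 T cells were compared next. Cytotoxicity and effector genes were higher in the arginine-deficient library and led by granzymes, the proteases that T cells release to kill targets. Exhaustion, cell cycle and cholesterol synthesis genes were lower. Of 20 cytotoxicity genes, 17 were higher, with a median log2 ratio of 0.30, above all 10000 random lists (percentile 100). Gzmd was at 1113 against 46.7 CPM, 23.8-fold (21.8–26.1), and Gzme at 658 against 35.5 CPM, 18.5-fold (16.7–20.6). The chemokines Xcl1 (173 against 269 CPM) and Ccl4 (2100.3 against 2403 CPM) were the lowest members. Gzmd, Gzme and Gzmf are neighbouring, near-identical copies on chromosome 14, so how their reads were divided is uncertain. The list was not higher in CD8 T cells alone, with medians of 1.10 in cDC1 cells (17 measured), 0.91 in neutrophils (12), 0.60 in tumour epithelial cells (6) and 0.32 in macrophages (9), all above random lists. The guard against free RNA was not applied to list members, so these values do not show that those cells made the transcripts. In CD8 T cells the median was 0.07 at 1 mix of the clusters, where the log2 ratios of Gzmd and Gzme were 2.67 and 2.46.

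Of 19 exhaustion genes, 13 were lower (median −0.21; percentile 0.01; −0.30 to −0.05 over the alternatives, the latter with doublets kept). Tox (ENSMUSG00000041272; chromosome 4, 6686353–6991557), a transcription factor that sustains the exhausted state, was at 410.2 against 1055 CPM, and Ikzf2, which encodes Helios, at 234 against 579 CPM. The inhibitory receptors Havcr2 (289.9 against 174 CPM) and Lag3 (225 against 148 CPM) were higher. Cd200r1 itself, the receptor, was at 16.5 against 31.4 CPM in these cells (log2 0.01 at resolution 0.5) and Cd200r4 at 19.6 against 24.9 CPM, so the list of CD200 and its receptors had a median of −0.28 over 3 measured genes (percentile 2.84). With list members held to at least 50 CPM that median rested on Cd200 alone (0.79).

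Naive, stem-like and memory genes were higher for 12 of 17 members (median 0.49; percentile 100). Il7r, the receptor chain for the survival cytokine IL-7, was 2.59-fold higher and Lef1, a transcription factor of naive cells, 2.58-fold higher. Bcl2, which blocks apoptosis, was at 371 against 688 CPM. The direction of the list's median turned at 1 mix of the clusters (−0.08) and, with other cells in the class, when doublets were kept or at resolution 0.5 (both −0.28). Within clusters the naive and memory median was 0.52 in L1, 0.17 in L3, 0.27 in L4 and −0.27 in L9. Of 14 activation genes 8 were higher (median 0.14; percentile 97.6; 0.00 at 1 mix and −0.09 without cluster L9), with Il2ra, the high-affinity IL-2 receptor chain, at 187 against 67.6 CPM and Myc, a driver of growth, at 38.4 against 70.7 CPM.

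All 23 measured cell cycle genes were lower in CD8 T cells of the arginine-deficient library (median −0.31; −0.84 at resolution 0.5 and −0.11 at 1 mix of the clusters), among them the replication licensing factors Mcm2 (33.1 against 55.8 CPM) and Mcm6 (48.2 against 76.4 CPM). Within clusters the cell cycle median was 0.22 in L1, −0.90 in L3, −0.45 in L4 and −0.22 in L9. The class leaves out cluster L5 (110 and 340 cells), which had the cell cycle genes Nusap1 and Hist1h1b among its leading genes. Over all alternatives, some of which keep L5 in the class, the cell cycle median lay between −0.84 and −0.11. Of 15 cholesterol synthesis genes 14 were lower (median −0.41, or −0.28 at resolution 0.5), with Cyp51, a sterol demethylase gene, at 16.4 against 39.1 CPM. No random list had a median as low as either list over the class. Hypoxia and glycolysis genes were lower for 19 of 23 (median −0.14; percentile 0.390; −0.02 with doublets kept), with Tpi1 at 192 against 253 CPM and the glucose transporter Slc2a3 the reverse, at 168 against 114 CPM. Dissociation stress genes were lower for 15 of 21 (median −0.20; percentile 0.01; −0.33 to −0.13 over the alternatives). Hspa1a (30.3 against 79.7 CPM) and Hspa1b (49.0 against 102 CPM), near-identical heat shock genes, were the lowest, and Ier3 was at 130.1 against 70.3 CPM.

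Genes that respond to arginine or to its lack differed little as groups in CD8 T cells. Of 15 arginine transport and metabolism genes 7 were higher and 8 lower (median −0.03; percentile 37.3). Slc7a1, the main cationic amino acid transporter of T cells, was at 84.7 (78.5–91.2) against 86.4 CPM (80.9–92.2), not distinguishable at this depth, while Srm, which makes spermidine, was at 6.33 against 13.7 CPM. Amino acid starvation response genes were lower for 12 of 15 (median −0.12; percentile 2.73; 0.02 at resolution 2). The lowest was Ddit4, an inhibitor of mTORC1, at 31.4 against 95.4 CPM, whereas Atf3 was at 128 against 101 CPM. Nuclear-encoded oxidative phosphorylation genes had a median of −0.01 (11 of 25 higher; percentile 33.0; 0.11 at resolution 2).

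Interferon gamma response genes were higher in CD8 T cells for 17 of 20 members (median 0.30; percentile 100), with the GTPase gene Gbp2 at 71.7 against 33.0 CPM. That median was 0.14 at 1 mix of the clusters, 0.11 at resolution 2, and 0.02 with doublets kept or at resolution 0.5. MHC class I antigen processing genes had a median of 0.07 (12 of 20 higher; percentile 88.4; 0.02 at 1 mix). Type I interferon response genes had one of −0.00 (9 of 19 higher; percentile 54.6), which was −0.22 at 1 mix of the clusters and −0.46 at resolution 0.5. Markers of other cells differed inside the CD8 T class as well. H2-Aa, an MHC class II gene of antigen-presenting cells, was at 137 against 77.5 CPM there and at 2754 against 1488 CPM in macrophages. C1qa, a macrophage gene, was at 70.7 against 89.98 CPM in CD8 T cells.

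Among single genes in CD8 T cells, Serpine2, a serine protease inhibitor, was 5.98-fold higher (5.26–6.80), Gzmf 4.07-fold, Penk, which encodes proenkephalin, 4.04-fold, and the chemokine Ccl1 3.85-fold. Serpinb9b, a serpin gene, Plcl1, Sfi1, a centrosome protein gene, and Spp1, which encodes osteopontin, were 3.03-, 2.70-, 2.57- and 2.45-fold higher. The lowest were Ier5l (67.6 against 253 CPM), Ddit4, Tox, the fatty acid desaturase gene Scd2 (31.3 against 79.7 CPM) and the linker histone gene Hist1h1e (63.7 against 150.2 CPM). Airn (116 against 265 CPM), Pkp4 (122 against 263 CPM), the kinase gene Dapk2, Nmt2 and the glycogen regulator Ppp1r3b followed, with log2 ratios from −1.16 to −0.94. Airn is annotated as antisense, so reads of its partner cannot be ruled out. Ppp1r3b turned with doublets kept (0.22) and at resolution 0.5 (0.10). Keeping doublets also brought Penk to 0.73, Ccl1 to 0.47, Plcl1 to 0.51, Ier5l to −0.96, Airn to −0.25 and Dapk2 to −0.18. The log2 ratios at 1 mix of the clusters were 1.204 for Serpine2 (2.38 in the class), 0.98 for Gzmf (2.002 in the class, 3.18 at resolution 2), 0.71 for Penk, 0.13 for Plcl1 and 0.52 for Serpinb9b, and Ccl1 stood at 0.35 without cluster L9.

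**Figure D3:**
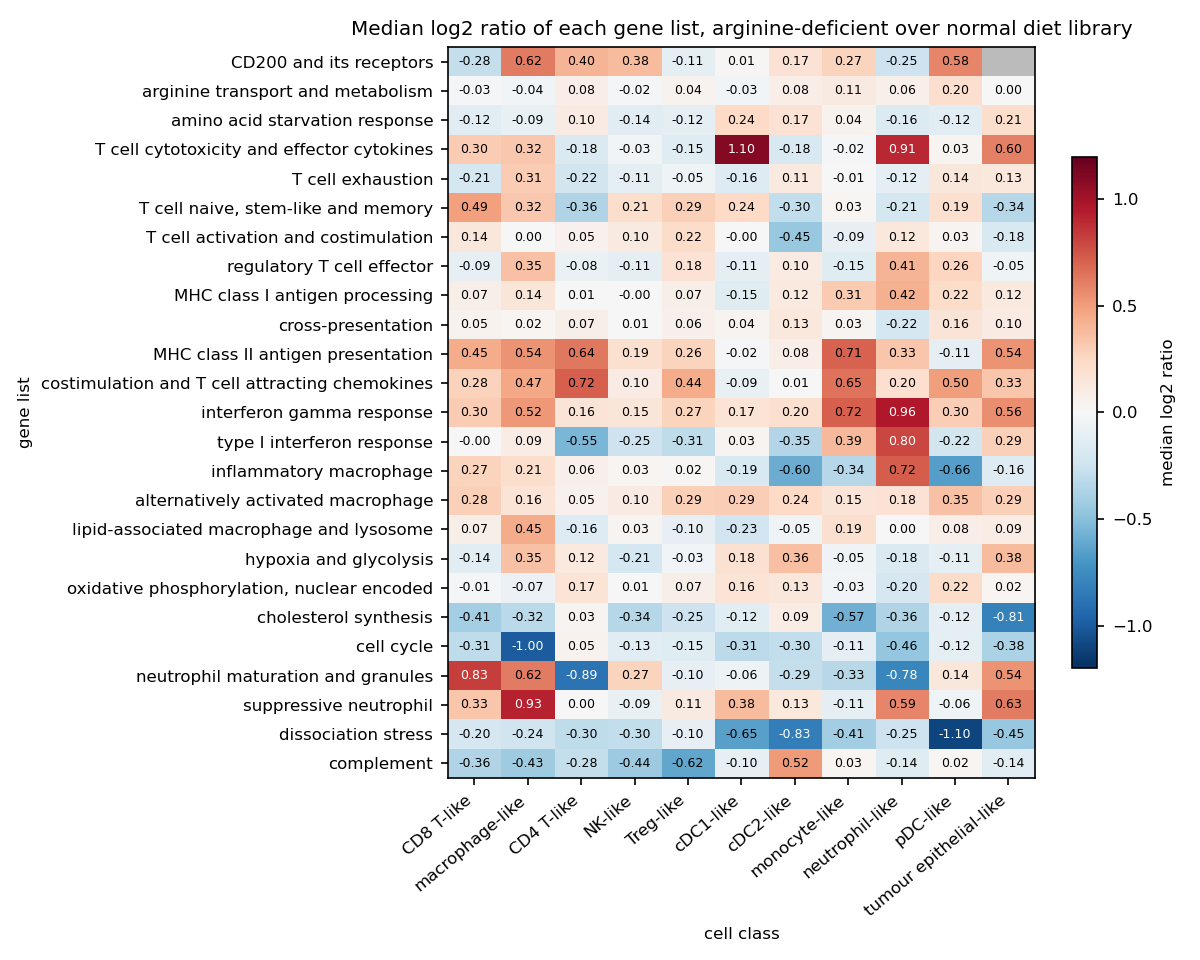
Heat map of the median log2 ratio (arginine-deficient over control library) of each of the 25 gene lists in 11 cell classes, red above and blue below 0, grey where no member was measured. Cytotoxicity genes in CD8 T cells stood at 0.30, and interferon gamma response genes were above 0 in all 11 classes.

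To describe the cells that the title names, CD8 T cells with and without a Cd200 UMI were compared inside each library. Cells with Cd200 carried more effector transcripts and fewer type I interferon response transcripts in both libraries. In the draw used for this, 204 cells with and 770 without Cd200 were compared in the arginine-deficient library, and 170 with 1127 in the control library. The cytotoxicity list had medians of 0.49 (16 of 20 higher) and 0.29 (13 of 18 higher), both at percentile 100, and under the stricter cell filter of 0.39 and 0.11. Ifng, the gene for interferon gamma, was at 995 against 421 CPM and at 1115 against 448 CPM, and the chemokine Ccl3 at 980.4 against 320.1 CPM and 882 against 452 CPM. None of the measured type I interferon genes was higher in cells with Cd200 (0 of 11, median −0.76, and 0 of 8, median −0.41). Gzma, a granzyme typical of less differentiated killers and NK cells, was at 49.0 against 323 CPM and at 11.8 against 208 CPM.

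Other groups differed between the libraries in this comparison. Exhaustion genes were higher with Cd200 in the arginine-deficient library (median 0.46; 15 of 16) and near random lists in the control library (0.08; 14 of 18; percentile 87.8). Naive and memory genes were lower in the former (−0.55; 5 of 15 higher; percentile 0) and inside random lists in the latter (0.15; 8 of 12 higher; percentile 97.2; −0.04 without thinning). The cells with Cd200 came mostly from cluster L4 in the arginine-deficient library (59.8%, with 36.3% from L9). In the control library they came from L1 (45.9%), L9 (31.8%) and L4 (20.6%). These contrasts therefore compare clusters as well as Cd200.

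Macrophages were compared to ask whether antigen presentation, and cross-presentation in particular, differed between the diets. Interferon gamma response, MHC class II, costimulation and chemokine, lipid-associated and glycolysis genes were higher in the arginine-deficient library. The cross-presentation list was not, and cell cycle genes were lower. All 22 interferon gamma response genes were higher (median 0.52; percentile 100), led by Nos2 and by Socs1, a feedback inhibitor of cytokine signalling (132 against 48.2 CPM). MHC class II genes were higher for 10 of 12 (median 0.54; percentile 100; 0.34 at 1 mix of the clusters, 0.89 with monocytes pooled), with the lysosomal protease gene Ctsl at 4017 against 1839 CPM and H2-Aa at 2754 against 1488 CPM. Costimulation and T cell attracting chemokine genes were higher for 12 of 14 (median 0.47; percentile 100). Pdcd1lg2, which encodes the inhibitory ligand PD-L2, was at 88.5 against 10.1 CPM and the chemokine Ccl5 at 519 against 95.6 CPM, with Cd83 at 204 against 249 CPM. In CD8 T cells of the arginine-deficient library, thinned, Ccl5 was at 4334 CPM without and 1946 CPM with a Cd200 UMI. Free RNA can therefore have added to its level in macrophages.

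Cross-presentation genes were split evenly, 12 higher and 12 lower, with a median of 0.02 (percentile 63.2). Lrp1 and Cd36, uptake receptors, were at 299 against 197 CPM and 243 against 180.3 CPM, whereas Rac2, which steers the phagosomal oxidase, was at 165 against 237 CPM and Hsp90aa1 at 378 against 513 CPM. Hsp90aa1 is also a member of the dissociation stress list, which was lower in macrophages. MHC class I antigen processing genes were higher for 15 of 20 with a median of 0.14, inside the range of random lists (percentile 94.7). Tapbp, the tapasin gene, was at 286 against 179 CPM, and Calr, which encodes the chaperone calreticulin, at 478 against 614 CPM. With monocytes pooled in, the medians were 0.10 for cross-presentation and 0.22 for MHC class I, at 1 mix of the clusters 0.13 and 0.18, and at resolution 0.5 0.10 and 0.37. The MHC class I median was lower, at 0.0852, with genes centred within libraries, at 0.0869 with doublets kept and at 0.0902 without a cell filter.

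Macrophage clusters also differed in size between the libraries. Cluster 0 held 50.1% and cluster 10 held 22.3% of the class in the arginine-deficient library, and cluster 1 held 40.5% in the control library. The interferon gamma list was above 0 inside clusters 0, 1, 6 and 9 (medians 0.87, 0.66, 0.81 and 0.40) and not in cluster 10 (−0.03). At 1 mix of the clusters it stood at 0.50. In clusters 0, 1, 6, 9 and 10 the MHC class I medians were 0.31, 0.20, 0.27, 0.13 and 0.04. Those of cross-presentation were 0.18, 0.13, −0.07, 0.04 and 0.01. No random lists were drawn within clusters.

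Lipid-associated and lysosome genes were higher for 21 of 24 (median 0.45; percentile 100), with the fatty acid binding protein gene Fabp5 at 2262 against 659 CPM and Trem2, a lipid receptor, at 301 against 331 CPM. All 24 hypoxia and glycolysis genes were higher (median 0.35; percentile 100), among them Egln3, a sensor of oxygen, at 52.7 against 15.3 CPM and hexokinase gene Hk2 at 196 against 85.5 CPM. All 24 cell cycle genes were lower (median −0.9997; Birc5, which encodes survivin, at 76.6 against 183 CPM). The medians at 1 mix of the clusters were 0.18 for the lipid-associated list (0.17 with monocytes pooled), 0.01 for glycolysis and −0.10 for the cell cycle. Cholesterol synthesis genes were lower for all 11 measured (median −0.32; Fdps 18.9 against 46.9 CPM), and complement genes for 7 of 10 (median −0.43, or −0.09 at 1 mix of the clusters and −0.68 with monocytes pooled), with C1qc at 1532 against 2755 CPM and C3 the reverse, at 157 against 41.8 CPM.

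Members of both macrophage activation programmes lay on both sides. Inflammatory genes were higher for 13 of 18 (median 0.21; percentile 98.9; 0.01 at 1 mix of the clusters, 0.48 with genes centred within libraries), with the neutrophil chemokine Cxcl3 at 497 against 147 CPM and Ccl2, which attracts monocytes, at 4076 against 5218 CPM. Alternatively activated genes were higher for 11 of 17 (median 0.16; percentile 93.6; 0.08 at resolution 0.5, 0.60 with doublets kept), with Retnla at 219 against 20.5 CPM, and Lyve1, a hyaluronan receptor of tissue-resident macrophages, at 14.8 against 84.8 CPM. Dissociation stress genes were lower for 14 of 21 (median −0.24; percentile 1.16; −0.10 with genes centred within libraries). Type I interferon and oxidative phosphorylation genes lay inside random lists (0.09 and −0.07, or 0.23 and 0.04 at 1 mix), but the type I interferon median was 0.46 with monocytes pooled and 0.43 under the stricter cell filter.

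The highest single genes in macrophages were Retnla, 10.7-fold (10.1–11.3), the matrix proteases Mmp9 (8.73-fold) and Mmp13 (4.73-fold), Inhba, a subunit of activin A (7.04-fold), and Pdcd1lg2 (8.72-fold). Rnase2a, Slc7a2, Nos2, Malt1, a signalling protease gene, and F10, which encodes coagulation factor X, were between 4.70- and 12.4-fold higher. F10 is also a monocyte marker by which clusters were named, and Inhba and F10 were among the leading genes of monocyte cluster 7. Their levels in macrophages thus depend on where the line to monocytes was drawn. The lowest were Cx3cr1, the fractalkine receptor gene (21.8 against 128 CPM), Ednrb, an endothelin receptor gene (20.5 against 116 CPM), Lyve1 and the transcription factor gene Klf2 (296 against 973 CPM). Histone genes (Hist1h1b, Hist1h2ae and H2afx), the creatine kinase gene Ckb, Ntpcr and Saa3 had log2 ratios from −1.54 to −1.26. Saa3, an acute phase gene, turned with doublets kept (0.07) and with genes centred within libraries (0.15). At 1 mix of the clusters several of these ratios were smaller, with log2 values of 1.40 for Mmp9, 1.27 for Inhba, 0.96 for F10, −0.38 for Hist1h2ae and −0.42 for Hist1h1b, and the value for Retnla was 4.01. With doublets kept, log2 values were 2.13 for Retnla, 1.25 for Rnase2a, −1.52 for Ednrb and −1.45 for Lyve1. Retnla stood at 1.57 and Rnase2a at 1.14 at resolution 2, and Mmp9 at 0.96 at resolution 0.5.

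Because the diets differ in arginine, the enzymes and transporters that handle it were followed across classes. In macrophages both arginases, inducible nitric oxide synthase and the inducible arginine transporter were higher in the arginine-deficient library. Arg1 (ENSMUSG00000019987; chromosome 10, 24915221–24927484), the arginase of myeloid cells, was at 1435 against 500.1 CPM, 2.87-fold (2.83–2.91), or 1.955-fold with monocytes pooled. Nos2 (ENSMUSG00000020826; chromosome 11, 78920787–78960254), which makes nitric oxide from arginine, was 5.50-fold higher (5.21–5.81; 144 against 26.2 CPM). Slc7a2 (chromosome 8, 40862396–40922308), an inducible arginine transporter, was 6.86-fold higher (119 against 17.3 CPM), and Arg2 and Ass1, which rebuilds arginine from citrulline, were 2.30- and 2.05-fold higher. Slc7a1 (ENSMUSG00000041313; chromosome 5, 148327410–148399904) was at 17.9 against 21.2 CPM and its direction turned in pooled cells (log2 0.02) and at 1 mix of the clusters (0.12). At that mix Arg1 had a log2 ratio of 0.59 against 1.51 in the class, and Nos2 one of 0.83 against 2.26.

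Outside macrophages Arg1 was at 429 against 458 CPM in monocytes (0.938-fold, 0.904–0.972), 258 against 130.2 CPM in neutrophils and 92.1 against 36.6 CPM in cDC2 cells. Nos2 was at 70.7 against 41.6 CPM in monocytes and 29.7 against 5.63 CPM in cDC2 cells, and Slc7a2 at 86.0 against 55.2 CPM and 84.2 against 13.1 CPM. Over the whole list macrophages had 8 members higher and 10 lower (median −0.04; percentile 32.9; 0.41 with members held to at least 50 CPM, 0.06 at 1 mix of the clusters), with Gatm, of creatine synthesis, at 453 against 843 CPM and Srm at 11.4 against 28.4 CPM. The amino acid starvation list in macrophages had 9 members each way (median −0.09, or 0.22 with the minimum of 50 CPM), with the cystine transporter gene Slc7a11 5.07-fold higher and Vegfa, a vessel growth factor gene, at 208 against 94.9 CPM.

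The receptor of CD200 was followed in the myeloid classes that could meet CD8 T cells. Cd200r1 (ENSMUSG00000022667; chromosome 16, 44765736–44794978) was 1.35-fold higher (1.29–1.42) in macrophages of the arginine-deficient library, at 76.3 against 56.6 CPM, and 1.24-fold higher with monocytes pooled. The related Cd200r4 was 1.92-fold higher, at 59.2 against 30.9 CPM. In monocytes Cd200r1 did not differ beyond counting error (67.7 against 63.0 CPM; 1.07-fold, 0.977–1.18), and neither did it in neutrophils (49.5 against 59.6 CPM). It was lower in cDC2 cells (117 against 147 CPM; 0.795-fold, 0.699–0.907) and higher in plasmacytoid dendritic cells (138 against 90.3 CPM). At 1 mix of the macrophage clusters the log2 ratio was 0.12, against 0.40 in the class.

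**Figure D4:**
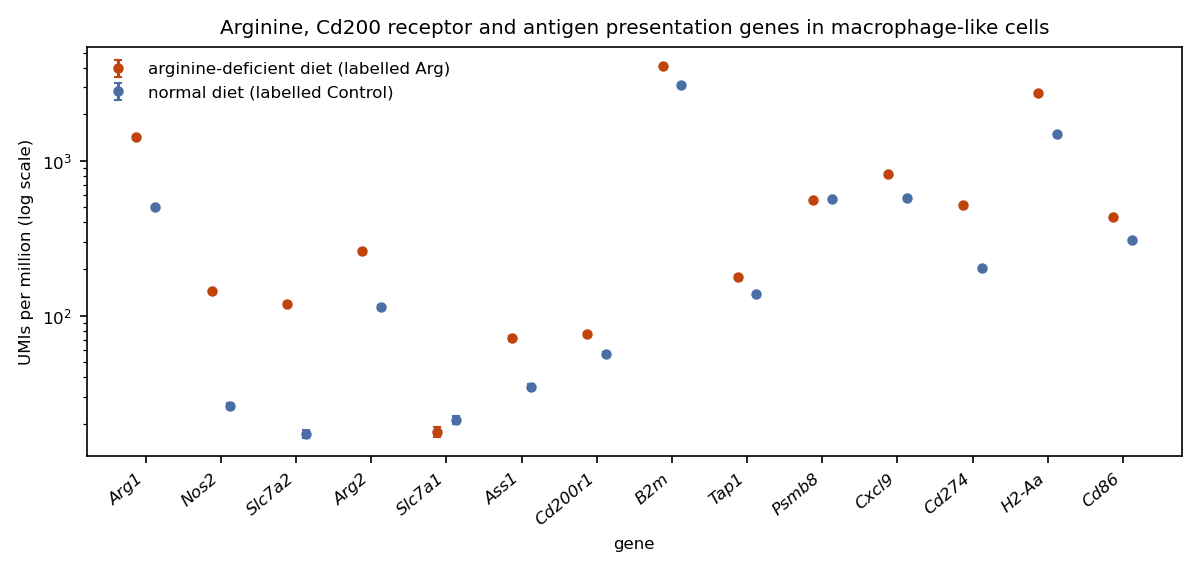
Levels (CPM on a log axis, points with exact Poisson 95% intervals) of arginine, Cd200 receptor and antigen presentation genes in macrophages of the arginine-deficient and control libraries. Arg1 stood at 1435 against 500.1 CPM, Nos2 at 144 against 26.2 CPM and Slc7a1 at 17.9 against 21.2 CPM.

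In the remaining lymphoid classes the sharpest differences were in CD4 T cells. Csf2, which encodes the myeloid growth factor GM-CSF, was at 816 against 32.2 CPM (25.3-fold, 15.9–42.9), Il13, a type 2 cytokine gene, at 331 against 14.3 CPM and Ccl1 at 120.4 against 5.37 CPM, on 232 and 114 cells. At resolution 2, where the CD4 T class had other cells, their log2 ratios were 0.78, 0.30 and 0.30, and Il13 and Ccl1 stood at 0.31 under the stricter cell filter. Hs6st3 and Hspa1a were among the lowest there. In regulatory T cells Itgae, an integrin of tissue-resident cells, was at 170 against 75.6 CPM, Pard3b and Sfi1 were also higher, and Ier5l, Nrn1 and Airn were lower. The regulatory T cell effector list was higher for 12 of 18 (median 0.18; percentile 99.9; 0.07 with equal weight per cell), with Il2ra at 1229 against 648 CPM and the ectoenzyme gene Entpd1 at 118 against 185 CPM. NK cells had higher Sfi1 (149 against 59.8 CPM), Sgk1 and Klf3, and lower Rgs16, Gadd45g and Hsph1.

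In myeloid classes monocytes of the arginine-deficient library had more Sfi1, Fabp5 (684 against 267 CPM) and Tent5c, and less Saa3 (4.73 against 80.4 CPM, 17.0-fold lower), Serpinb2 and Cxcl3 (381 against 1217 CPM). Without a cell filter the log2 ratios of Fabp5, Saa3 and Serpinb2 were 0.65, −1.62 and −0.66, and that of Cxcl3 was −0.53 at resolution 0.5. Neutrophils had lower maturation and granule genes (10 of 13 lower; median −0.78; percentile 0.01), with Retnlg at 152 against 1088 CPM. They had higher suppressive genes (14 of 16; median 0.59; percentile 100), with Cd274, which encodes PD-L1, at 2576 against 1150 CPM. Mmp13, Mmp12 (898 against 214 CPM) and Gbp5 were their highest single genes, and Mnd1 (1 against 70 UMIs; 31.1-fold lower, 5.40–1245) and Plcb1 (log2 −3.01, or −1.35 with doublets kept) their lowest. In cDC2 cells Inhba (192 against 30.0 CPM), Rnf217 and Slc7a2 were highest. Ltc4s, Klf2 and Ccl24 were lowest. Without a cell filter Inhba stood at 0.28 and Ltc4s at −1.54, and Ccl24 turned without a cell filter (0.89) and with genes centred within libraries (0.74).

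Plasmacytoid dendritic cells had lower Egr1 (82.3 against 472 CPM), Fosb and Ier2 and higher Socs2, Cables1 and Sfi1. The cDC1 class had lower Hspa1a (166 against 571 CPM), Hspa1b and Chrm3 and higher Edil3, Itga1 and Fgf13. Tumour epithelial cells had higher Car6, a secreted carbonic anhydrase gene (92.1 against 6.99 CPM), Slurp1 and Aldh1l2, and lower Sncg, Idi1 and Klf2.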

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

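The tests at 1 mix of clusters were chosen only after the results were seen. The 5 results described here drew attention because the same gene list lay above 0, outside its random lists, in one class and below 0, outside its random lists, in a related class. With 1 library per diet none of these differences between classes was tested, and no explanation is offered for them.

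Naive, stem-like and memory genes had a median log2 ratio of 0.49 in CD8 T cells (12 of 17 higher in the arginine-deficient library) and of −0.36 in CD4 T cells (3 of 18 higher). At 1 mix of the clusters the CD8 T value was −0.08. Inflammatory macrophage genes had medians of 0.21 in macrophages (13 of 18 higher) and −0.34 in monocytes (4 of 18 higher), and the macrophage value at 1 mix of the clusters was 0.01.

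The other 3 results rest on few genes. Regulatory T cell effector genes had medians of 0.35 in macrophages (8 measured) and −0.15 in monocytes (6 measured). Neutrophil maturation and granule genes had medians of 0.62 in macrophages (5 measured) and −0.33 in monocytes (8 measured). In CD8 T cells 2 genes of that list, Cxcr4 and Anxa1, were measured, with a median of 0.83, and the same pair had a median of −0.89 in CD4 T cells.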

How the results depend on the processing

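The tests named here as added were chosen only after the results were seen; all others were planned. No paired analysis was possible because each diet has 1 library, and for the same reason no library was left out in turn. Of 2001 alternative values for 161 results, 1374 stayed within the counting interval of the value reported and 19 reversed. The other 608 lay outside it in the same direction or belonged to results that were not called. A gene list of a class was called where its median lay outside random lists. Any other result was called where its counting interval excluded 0, or 1 for the ratio of Cd200-positive shares. Of 144 called results, 133 never reversed. Single genes made up 101 of the 144, most of them picked for extreme log2 ratios, so that count does not measure robustness. Values are log2 ratios or list medians unless named otherwise. Depth limits values from small clusters, as in CD8 T cluster L3, where 7 and 5 Cd200 UMIs gave a fold of 0.756 (0.207–3.02).

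With the stricter cell filter the macrophage share was −0.66, macrophage MHC class I genes 0.18, interferon gamma genes 0.60 and Arg1 1.45. Without a filter these were −0.28, 0.0902, 0.41 and 1.59, Cd200r1 in macrophages 0.62 and Ccl24 in cDC2 cells 0.89 (reversed; the cause was not tested).

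With doublets kept the CD8 T share reversed (1.004), as it did at resolution 0.5 (1.10), because CD8-positive clusters with a gamma-delta T marker among their leading genes lose their name there by construction. It reversed at resolution 2 as well (0.0464; the cause was not tested). The classes then hold other cells, so the values that follow differ too. With doublets kept the macrophage share was −0.31, the ratio of Cd200-positive shares 1.08, Cd200 0.14, the cytotoxicity list 0.18, macrophage MHC class I genes 0.0869, interferon gamma genes 0.39, Cd200r1 0.66 and Arg1 1.66. The naive and memory list (−0.28), Ppp1r3b (0.22) and Saa3 in macrophages (0.0654) reversed. At resolution 0.5 the macrophage share was −1.24, Cd200 0.12, cytotoxicity 0.16, and in macrophages MHC class I 0.37, cross-presentation 0.10, interferon gamma 0.79, Cd200r1 0.26 and Arg1 0.76. The ratio of Cd200-positive shares (0.952), the naive and memory list (−0.28), Ppp1r3b (0.10) and Cd200r1 in CD8 T cells (0.0092) reversed. At resolution 2 cytotoxicity was 0.21 and, in macrophages, interferon gamma 0.50, Cd200r1 0.53 and Arg1 1.47.

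With genes centred within libraries the macrophage share was −0.0334, MHC class I 0.0852, cross-presentation 0.0553, interferon gamma 0.38, Cd200r1 0.67 and Arg1 1.69, and Saa3 in macrophages (0.15) and Ccl24 in cDC2 cells (0.74) reversed; the cause was not tested. Under TMM and median-of-ratios scaling, which shifted the median of all genes by −0.02 in macrophages, interferon gamma was 0.50 and 0.50 and Arg1 1.49 and 1.49. With equal weight per cell cytotoxicity was 0.15, MHC class I 0.10, interferon gamma 0.42 and Arg1 1.48. With a list minimum of 50 CPM interferon gamma was 0.53. Without thinning the naive and memory list of cells with Cd200 in the control library reversed (−0.0441); the cause was not tested.

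Of the added settings, not counting markers of the same lineage gave a CD8 T share of −0.59 and cytotoxicity of 0.41, with doublets kept −0.61 and 0.41, and at resolution 0.5 −0.59 and 0.41. Without cluster L9 the CD8 T share was −0.53 and the activation list reversed (−0.0917; fewer cells by construction). Among immune cells the CD8 T and macrophage shares were −0.53 and −0.57. At 1 mix of the clusters Cd200 was 0.15, cytotoxicity 0.0737, MHC class I 0.18, cross-presentation 0.13, Cd200r1 0.12 and Arg1 0.59, while the naive and memory list (−0.0789) and Slc7a1 in macrophages (0.12) reversed, as the difference in mix is removed by construction. With monocytes and cluster 2 pooled in, the macrophage share (0.11, with a ratio of 0.987 among immune cells) and Slc7a1 (0.0239) reversed, since other cells enter by construction. In that pool MHC class I was 0.22, cross-presentation 0.10, interferon gamma 0.74, Cd200r1 0.29 and Arg1 0.96.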

Other observations

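For Cd200 in CD8 T cells the tests of the cluster mix and of free RNA, for Ifng the scaling per kept UMI, and for the stress genes the test of tissue handling, were chosen only after the result was seen.

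Several gene groups lay on the same side in most of the 11 classes with at least 100 cells per library. Interferon gamma response genes had a median above 0, and above the central 95% of random lists, in all 11 (from 0.15 to 0.96). The guard against free RNA was not applied to list members. Cxcl9, at 824 against 576 CPM in macrophages, was at 27.3 against 12.4 CPM in NK cells. The CD8 T median was 0.02 with doublets kept or at resolution 0.5. These medians thus do not show a response in every class. Type I interferon response genes did not lie on 1 side, with medians above 0 in 5 classes and below 0 in 6. They lay below their random lists in CD4 T cells (−0.55), cDC2 cells (−0.35), regulatory T cells (−0.31), NK cells (−0.25) and plasmacytoid dendritic cells (−0.22), and above them in tumour epithelial cells (0.29), monocytes (0.39) and neutrophils (0.80). Cell cycle genes lay below 0 in 10 of 11 classes and cholesterol synthesis genes in 9. The single gene Sfi1 was higher in all 11 classes (log2 ratio 0.29 to 1.49), and the transcription factor gene Klf2 was lower in all 11 (−2.46 to −0.29).

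Cd200 was 1.77-fold higher in CD8 T cells of the arginine-deficient library. Free RNA as the whole cause is argued against, because the libraries differed in NK cells by 0.243 CPM (−1.27 to 1.76), far from the 71.2 CPM in CD8 T cells. The background differed more in macrophages (7.75 against 1.70 CPM) and in neutrophils (12.4 against 5.49 CPM, on 7 UMIs each). A small part from free RNA therefore stays open. Doublets with mature dendritic cells, the class richest in Cd200, are also argued against, as their 8 markers stood in CD8 T cells at a median of 0.396% of their own level where 22.5% would be needed. At 1 common mix of the CD8 T clusters the fold was 1.11 (0.988–1.25). Thus 81.2% of the log2 fold was gone, or 68.4% with cluster L5, and the mix may account for much of the difference. Whether it is the whole of it cannot be told apart from higher levels within clusters, because with cluster L5 the fold was 1.22 (1.11–1.35), and an effect of the diet on that mix stays open with 1 library each.

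Interferon gamma response genes were higher in macrophages of the arginine-deficient library (median 0.52). The mix of macrophage clusters as the whole cause is argued against by a median of 0.50 at 1 mix (random lists −0.04 to 0.16). The line drawn against monocytes is argued against by a median of 0.74 with both and the unnamed cluster 2 pooled (random lists −0.12 to 0.22). That pool also carries the larger share of cluster 2 (11.5% against 4.21% of cells), which had Cxcl9 among its leading genes. No pool without cluster 2 was made. TMM and median-of-ratios scaling shift all genes of a class alike, by −0.02 in macrophages, so they could hardly change the list's place among random lists. With equal weight per cell the median was 0.42, the lowest over 3 other scalings. It lay above the random lists of the main scaling (−0.14 to 0.17), which argues against the weighting of cells as the whole cause. Random lists were not drawn under equal weight. More Ifng transcript from T and NK cells stays open. Their Ifng UMIs had a ratio of 0.962 (0.934–0.990; 8845 against 9062 UMIs) per kept cell, below 1 as the bound set beforehand asked. That bound ignored depth. Per kept UMI the ratio was 1.23 (1.19–1.27), but this scaling does not correct for the depth of T and NK cells alone. It divides by the UMIs of all kept cells. Tumour epithelial cells, with medians of 39499 and 37314 UMIs, were 3.22% and 9.49% of these. Fewer tumour UMIs in the arginine-deficient library raise that ratio, so it does not by itself show more Ifng. Ratios per class UMI lay on both sides of 1. They were 1.23 in CD8 T, 0.913 in NK, 0.934 in CD4 T and 0.935 in regulatory T cells. A response of macrophages to the diet or to that transcript remains a hypothesis that may be checked with replicate mice, and interferon gamma protein was not measured.

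Dissociation stress genes had medians below 0 in 11 of 11 classes of the arginine-deficient library (−1.10 to −0.10), and in 9 of these, regulatory T cells and neutrophils excepted, below their random lists. Under the stricter cell filter, which asks for at least 500 genes and at most 5% mitochondrial UMIs, the median over classes was −0.42, against −0.30 under the main filter. This argues against damaged cells over that mitochondrial limit as the whole cause. Damaged cells under the limit stay open, because the filter keeps them. Tissue handling that differed between the preparations could give such a pattern in every class, and with 1 preparation per diet handling and diet cannot be told apart.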
